A study of Caenorhabditis elegans with 4 samples.

How the data were processed

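Fed L1 larvae of strain OP109 were grown at 20 °C on bacteria, crosslinked with 2% formaldehyde and quenched with 100 mM Tris, per the labels' protocols. Chromatin was sonicated, and fragments carrying the GFP-tagged factor were recovered with an affinity-purified goat antibody against EGFP. The 4 libraries fell into 2 groups by their descriptions, BLMP-1 ChIP with 2 libraries and input DNA with 2, from 2 extractions. Whether the extractions came from separate cultures is not stated.

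The deposited values were 1 list of peaks called with PeakSeq on WormBase build WS180, per the file headers and source column. PeakSeq scores regions of ChIP reads against input reads. Each peak had a start, an end and a q-value, which the authors deposited as its score and which ran up to 0.01. Apart from tag counts that were later inferred from it, the q-value was used here only to describe and rank peaks within the list. It measures the strength of evidence, which grows with read number and so with peak width, and is not an enrichment. The list carries the word combined, and whether reads were pooled or separate calls merged is not given in the sources used here. The aligner, the version of PeakSeq, read filters and the number of reads are likewise not given in the sources used here. Depth per library is therefore unknown, and no value could be compared between replicates.

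The gene table in hand was of assembly WBcel235 and the peaks are on WS180. Coordinates of different builds were not combined. The planned comparisons of peaks with genes, promoters, transcription start sites, fixed gene lists and sequence words were set to run only with a genome and annotation of the same build, and they were not run. The rule for named items was the 25 highest-scoring promoter genes, or, without an annotation of the build, the 25 strongest peaks by coordinate, and the latter applied. Peaks named outside this rule were chosen after their values were seen. Chromosome lengths of WS180 were not used here, so the span from the start of the leftmost peak to the end of the rightmost stood in for length. This makes chromosomes too short. At the left ends it does so most on X, whose leftmost peak starts at 295645, and the length missing at the right ends is unknown.

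Peaks were assigned to positions by their midpoints. Peak counts were compared with spans by a chi-square test, by exact two-sided binomial tests of each chromosome against the rest and by 1000 random placements. The central part of a chromosome ran from 0.25 to 0.75 of its span, and its share of peaks was tested against 50% by an exact two-sided binomial test. The chi-square test, the random placements, the test of the central share and the alternatives to them were fixed before the data were examined. The binomial tests of each chromosome against the rest were not part of that plan. The plan also held exact Poisson intervals of the densities, which treat peaks as independent and are not printed here. Because peaks cluster, a rotation test and a block bootstrap were added after the data were seen. The rotation test shifted all peaks of a chromosome together by a random distance, with the ends joined, 10000 times. The bootstrap resampled blocks of 500 kb 2000 times, cut at the edges of the central part where shares were computed. Medians were compared by permutation with 100000 resamples, two-sided. Intervals are at the 95% level. Benjamini-Hochberg adjustment was over the 6 chromosomes.

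The tests were tested on simulated data. With 1600 peaks placed in clusters and no central excess, the binomial test gave p-values under 0.05 on 59.0% of 200 simulated chromosomes and the rotation test on 3.5%. With 30% of the peaks or clusters moved to the centre, rotation gave them on 99.5% where peaks were placed uniformly and on 35.5% where they were clustered, so on single chromosomes it can miss a central excess. The simulated clusters had 1 fixed size that was not fitted to the list, so these rates need not hold for it. Results were recomputed with lists restricted by q or width, with peaks closer than 200 bp merged, with a narrower central part, and, added later, with a list restricted by a ratio of ChIP to input tags inferred from the q-values. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.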

Results

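BLMP-1 is a zinc-finger transcription factor of Caenorhabditis elegans and the relative of vertebrate PRDM1 (Blimp-1). Its binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in fed larvae of the L1 stage, the earliest larval stage after hatching. The worms were hermaphrodites of strain OP109, which carries a transgene of blmp-1 fused to EGFP together with a rescuing unc-119 copy in an unc-119 mutant background. There were 2 ChIP libraries, made with a goat antibody against GFP, and 2 libraries of input DNA from the same extractions. The question was where in the genome the tagged factor was recovered. The values analysed were 10159 peaks in 1 combined list over both replicates, placed on WormBase build WS180, each with the q value of the peak caller. The list held no value of a single library, so no replicate error could be given and the sequencing depth is unknown. The intervals and p-values that follow describe how peaks were spread within this list, and do not cover differences between worms or libraries.

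BLMP-1 peaks lay on all 5 autosomes and on X, and 0 were listed on the mitochondrial genome or other sequences. They had a median width of 421 bp, with quartiles of 309 and 619 bp, and covered 5.46 Mb, or 5.475% of the 99.732 Mb between the outermost peaks of the chromosomes. Widths ran from 1 to 20797 bp, with 13 peaks of at least 5000 bp and 185 of at most 50 bp. The authors' q values ran from 6.50e-294 to 0.01, with a median of 8.92e-11 and quartiles of 6.08e-26 and 1.98e-05. A q under 1e-100 was listed for 305 peaks and a q under 1e-20 for 3111, while 1109 peaks had a q over 0.001. Peaks of lower q were wider. The median width was 943 bp for the peaks with q under 1e-100 and 269 bp for those with q over 0.001, and Spearman's rho between width and −log10 q was 0.56 across peaks, which are not independent replicates. Neighbouring peaks on a chromosome were separated by a median of 3415 bp, by at least 200 bp and by at most 369153 bp.

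The 25 peaks of lowest q were spread over all chromosomes, with 5 each on I, II and X, 4 on V and 3 each on III and IV. These are the lowest q values of the list analysed. The spacing of its q values left room for 12 ranks at the top that were not analysed here. All coordinates are on WS180, and the genes at these positions were not analysed here. The lowest q, 6.50e-294, belonged to a 3132 bp peak on chromosome V from 8038564 to 8041695. It was followed by a 1440 bp peak on II from 6711877 to 6713316 (q = 6.77e-292) and a 1410 bp peak on I from 527109 to 528518 (q = 1.48e-269), the latter on a chromosome arm. On X, the lowest q was 2.39e-258, at 9546618 to 9553505, and this peak of 6888 bp was the widest of the 25. Chromosome III had its lowest q, 1.12e-246, at 6358487 to 6361863, and chromosome IV its lowest, 4.29e-218, at 14089251 to 14090270. On II, the peaks from 6711877 to 6713316 and from 6713539 to 6714378 (q = 1.75e-249) were only 222 bp apart. On V, the peaks from 12525516 to 12526603 (q = 1.54e-205) and from 12551493 to 12554892 (q = 1.44e-226) were 24889 bp apart.

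The other members of the 25 had q values up to 4.29e-199. On I they lay at 9944962 to 9946643, 6339829 to 6341496, 6868119 to 6869296 and 7216144 to 7218193. Those on II lay at 8748813 to 8749729, 6978753 to 6980016 and 6842062 to 6845453, and those on III at 9646077 to 9646966 and 5836140 to 5842162. Chromosome IV held the peaks at 9533914 to 9535546 and 8526740 to 8529758, and chromosome V the peak at 6105047 to 6105883. The remaining peaks on X lay at 4808303 to 4810632, 3837182 to 3838285, 2212675 to 2217578 and 2590625 to 2592249. The 25 had a median width of 1633 bp (range 837 to 6888), and 21 were wider than 1000 bp. Of the 25, 20 lay in the central part of their chromosome, from 0.25 to 0.75 of its span.

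The chromosomes were compared by peak density. Chromosome III was the densest, with 1649 peaks or 120 per Mb (95% interval of a 500 kb block bootstrap 105 to 134), and V the sparsest, with 1638 peaks or 78.4 per Mb (65.4 to 92.3). Chromosome I had 1709 peaks, 114 per Mb (101 to 128), and II had 1691, 111 per Mb (93.9 to 128). Chromosome IV had 1724 peaks, 98.9 per Mb (85.25 to 112.2), and X had 1748, 100.0 per Mb (92.4 to 109). Counts departed from proportionality to span (chi-square 192.6, p = 1.10e-39). In 1000 random placements, V drew 2007 to 2263 peaks and III 1304 to 1526, against 1638 and 1649 observed. The counts on I and II lay above the highest random counts, 1637 and 1652. Those on IV and X lay within the random ranges, 1662 to 1902 and 1650 to 1902.

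Peaks were clustered, and the variance of the counts in 195 blocks of 500 kb was 8.75 times their mean. That ratio also holds the differences between chromosomes and between centres and arms. Short gaps were in excess even over random placements that moved each peak by up to 500 kb, as given below. Tests that treat peaks as independent therefore give p-values that are too small. Relative to the rest of the genome, the density on V was 0.725 (two-sided exact binomial p = 7.07e-35; bootstrap 0.594 to 0.85) and on III 1.21 (exact p = 2.90e-12; 1.05 to 1.38). Both bootstrap intervals excluded 1. The ratio on I was 1.14 (exact binomial p = 5.32e-07; 0.987 to 1.31) and on II 1.1 (p = 2.10e-04; 0.921 to 1.29), so that neither was distinguishable from the rest once clustering was allowed for. The ratios on IV, 0.965 (exact binomial p = 0.187; 0.824 to 1.1), and X, 0.982 (p = 0.497; 0.887 to 1.08), were not distinguishable from 1 by either measure. Among the 5079 peaks of highest ratio of ChIP to input tags, a ratio inferred from the q values and a setting chosen after the data were seen, the density on X was 0.819 of that on the autosomes (exact binomial p = 2.49e-07, bootstrap 0.717 to 0.935). Inferred input, the denominator of that ratio, was higher on X in peaks of at least 200 bp (medians 356 and 310 tags per kb). This lower density therefore cannot be read as weaker binding. No difference between chromosomes was detected in how many of their peaks belonged to the strongest 25% by q (24.1% on V to 25.9% on X; chi-square 2.01, p = 0.848).

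**Figure D1:**
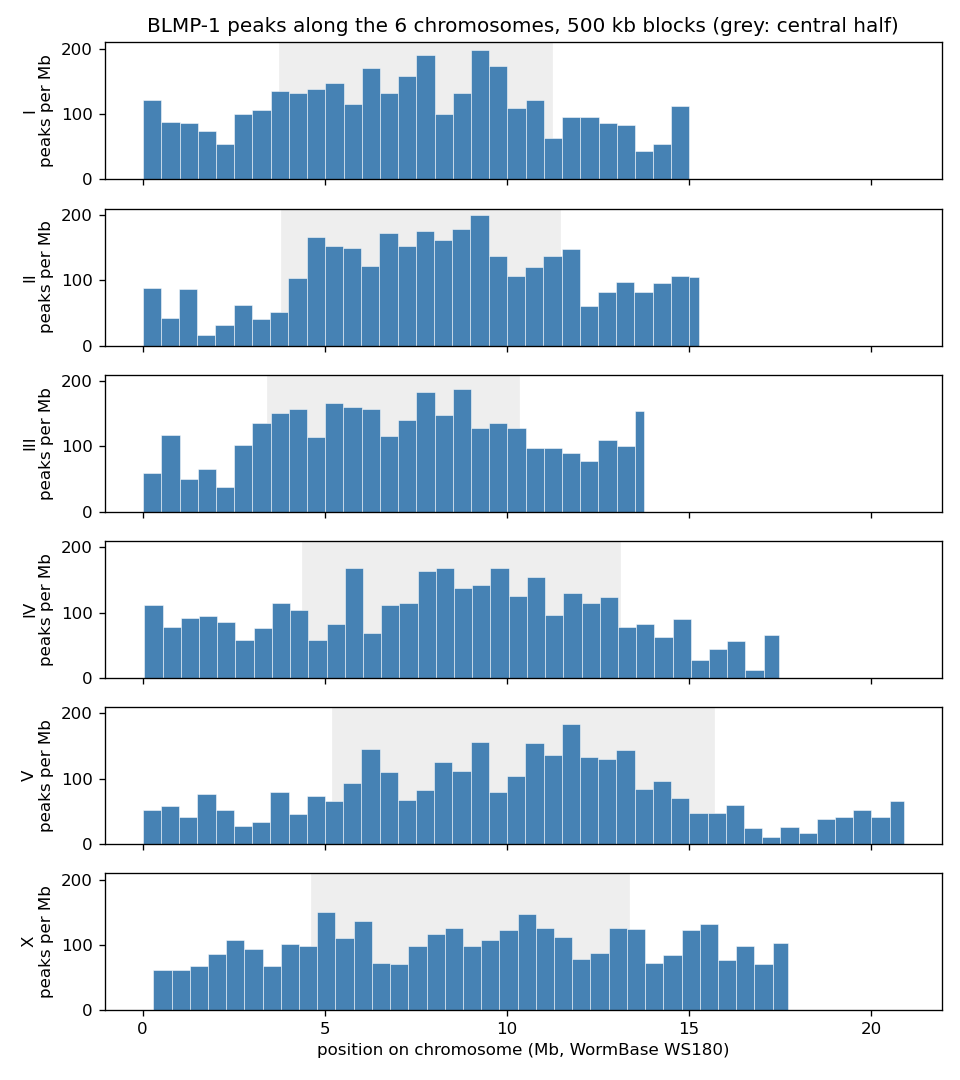
BLMP-1 peaks per Mb (vertical axis) in consecutive 500 kb blocks along each chromosome (horizontal axis, position in Mb on WS180), with the central part of each chromosome in grey; the last block of a chromosome is shorter and is scaled to its own length. Full blocks range from 5 peaks (10 per Mb) on the right arm of V to 100 peaks (200 per Mb) on II.

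Density also varied within chromosomes. The median block of 500 kb held 50 peaks. The densest lay on II from 9001358 to 9501357, with 100 peaks, followed by I from 9016826 to 9516825, with 99. The sparsest lay on the right arm of V from 17007780 to 17507779, with 5 peaks, and on the right arm of IV from 16549806 to 17049805, with 6. The longest gap between neighbouring peaks, 369 kb, was also on V, from 17345220 to 17714372. The next longest such gap was on V from 2285514 to 2573500, 288 kb, and then on X from 1712777 to 1960865, 248 kb. Stretches beyond the outermost peaks are not counted among these gaps, and X had no peak before position 295645.

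Chromosome centres and arms were compared because the centres of C. elegans autosomes hold more genes per length than the arms. On the autosomes, 5458 of 8411 peaks (64.9%; bootstrap 62.9 to 66.9) lay in the central part, which makes up 50% of the span. This was 133 peaks per Mb in the centres and 71.8 in the arms, a ratio of 1.85. The p of 10000 rotations of the peak positions along the autosomes was 0.0001, the smallest they can give. Over all 6 chromosomes the share was 63.3% (two-sided exact binomial p = 9.98e-160; rotation p = 0.0001; bootstrap 61.5 to 65.0).

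The centre held more peaks per Mb than the arms on 6 of 6 chromosomes. The central share was highest on V, 70.2% (bootstrap 65.6 to 74.2), and II, 66.6% (61.9 to 71.6). It was 63.5% on IV (59.4 to 67.7), 62.2% on III (58.0 to 66.5), 62.1% on I (58.3 to 66.1) and 55.5% on X (52.2 to 58.7). The centre to arm ratio of density ran from 2.36 on V through 2.0 on II, 1.74 on IV and 1.64 on both I and III to 1.25 on X. The planned exact binomial test gave adjusted p-values from 7.20e-61 on V to 3.82e-06 on X (Benjamini-Hochberg over 6 chromosomes). Rotation, which keeps the clustering, passed no single chromosome after the same adjustment, with 0.0543 on IV and X, 0.102 on III and 0.184 on I, II and V. It gave unadjusted p-values under 0.05 on IV (0.0181) and X (0.0179). Rotation compares a chromosome only with its own shifted peaks, so its p reflects how well dense stretches line up with the centre. It does not measure the size of the excess: V, with the highest share, had an unadjusted rotation p of 0.184.

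**Figure D2:**
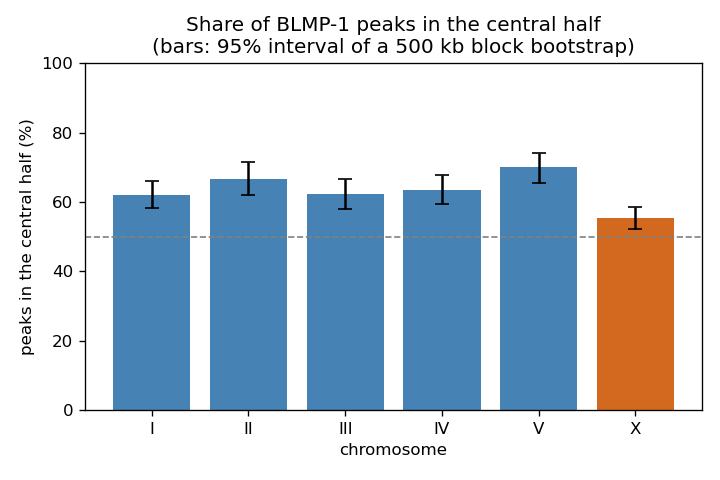
Share of BLMP-1 peaks in the central part of each chromosome (vertical axis, %) for the 5 autosomes (blue) and X (orange); black bars are 95% intervals of a 500 kb block bootstrap and the dashed line marks the 50% of the span that the central part makes up. All 6 shares lie above the line, from 55.5% on X to 70.2% on V.

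X was set against the autosomes in comparisons chosen after the data were seen. The central share was 9.34 percentage points lower on X, 55.5% against 64.9%, and X lay below 5 of 5 autosomes. Fisher's exact test gave p = 3.02e-13 and the bootstrap 5.61 to 13.4 points, but rotation gave p = 0.11. Rotation shifts each chromosome separately, the autosomes included. It asks how often such a difference arises when dense stretches line up with the centres only by chance on every chromosome. The bootstrap asks how far the difference varies between blocks. Both allow for clustering but answer different questions, and the difference did not hold in each of them. Peaks on X were wider, with a median of 470 bp against 412 bp, a difference of 58 bp (bootstrap 41.5 to 72.0; two-sided permutation p = 1e-05, the smallest possible). Their −log10 q was not distinguishable from that of autosomal peaks, with medians of 9.92 and 10.09 (permutation p = 0.647; bootstrap of the difference −0.808 to 0.612).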

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

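The restriction by the inferred ratio of ChIP to input tags, rotation and the block bootstrap, and every setting of the comparisons of X, were chosen after the data were seen. Merging peaks closer than 200 bp tested nothing, since the smallest gap was 200 bp, and rotation and the bootstrap change only the error. Of the 49 values recomputed under the other alternatives, 42 were counted as kept in direction and side of the threshold, and 0 reversed. Among the 42 were a median width (422 bp) and a number of peaks (9144), which have no threshold. The side of the threshold was judged by binomial or Fisher's exact tests, which treat peaks as independent and give p-values that are too small. Of the rest, 3 were numbers of peaks in shortened lists. The density on V stayed below that of the other chromosomes in the 4 alternatives that could move it (ratios 0.665 to 0.73; bootstrap over all peaks 0.594 to 0.85), and the central share stayed 1.27 to 1.38 times its expectation in the 5 that could, with the centre defined as the middle 33.3% of the span giving 1.33. By the binomial test, all 24 central shares of single chromosomes stayed above 50%. Under rotation, no single chromosome passed after adjustment. Rotation had little power on the clustered peaks of the simulation, and its p on a single chromosome does not measure the size of the excess. Median width moved from 421 bp to 526 bp in the 5079 peaks of lowest q, to 739 bp in the 1015 of lowest q and to 395 bp in the 9144 narrower peaks, since q falls with width and the last leaves out wide peaks by construction. It was 422 bp in the 5079 peaks of highest inferred ratio of ChIP to input. The density ratio of X to the autosomes, 0.982 over all peaks, fell to 0.819 (exact binomial p = 2.49e-07; bootstrap 0.717 to 0.935) in the 5079 peaks of highest inferred ratio of ChIP to input, and the cause was not tested. The lower central share of X, 9.34 points, passed Fisher's exact test, and its bootstrap interval (5.61 to 13.4 points) excluded 0, but it did not pass rotation (p = 0.11). The bootstrap and rotation both allow for clustering and answer different questions. Densities per 1000 protein-coding genes, shares of genes with promoter peaks in arms and centres, and all alternatives for genes, start sites, gene lists, promoter peaks and sequence words were not run, because no annotation or genome of WS180 was used here. No paired analysis was possible because the list gives 1 combined value per peak and none per library, and for the same reason no replicate could be left out. Unknown depth limits what the list can show of weak sites.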

Other observations

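The tests below were chosen after the results were seen, except those of input coverage on the arms and of gaps from 1 to 3 kb, which were specified before their results were seen. Peaks of BLMP-1 lay in groups. Of the gaps between neighbours, 47.3% were under 3 kb, and the median gap was 3415 bp. In 1000 placements that moved each peak at random by up to 500 kb, the median gap was 6196.5 to 6689 bp. Random gaps under 200 bp were left out, since the list has none, and this raises the random medians. Gaps from 200 to 500 bp numbered 1180 against a mean of 314.4 at random, and gaps from 500 to 1000 bp 1388 against 499.9. Joining peaks less than 1 kb apart gave 63 groups of at least 5. The group with most peaks lay on II from 6820259 to 6839356, with 12 peaks in 19.1 kb and a lowest q of 4.04e-161. It was followed by V from 14498102 to 14508670, with 10 peaks in 10.6 kb, and III from 2868459 to 2876574, with 9 peaks in 8.12 kb.

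The grouping may come from single bound regions that the caller split into several peaks. Gaps of 1 to 3 kb numbered 2232, above the highest of the random placements (1840), and this had been set beforehand as evidence against splitting. That criterion was wrong by design, because the list holds only called stretches, and a broad region split by the caller and separate sites would give the same gaps. Listed peaks at least 3000 bp wide (56) show that such lengths occurred but not how many regions were split, so the count leaves splitting open. Stretches of dense sites or genes shorter than 500 kb also stay open, since the placements even these out.

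The central excess on the autosomes may be technical. Weak calls alone are argued against, since 70.4% of the autosomal peaks in the strongest 10% by q were central, and in the weakest 25% the share was 57.0%. The exact 95% interval of the former, 67.2 to 73.5, treats peaks as independent and is therefore too narrow. Lower coverage of the arms could not be settled, because inferred input tags per kb in arm peaks were 0.963 times those in central peaks (bootstrap 0.921 to 1.0), and only called peaks could be examined. No biological explanation was tested, and the higher gene density of autosome centres stays open.

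The q values of the list may hold tag counts. PeakSeq compares ChIP tags with scaled input tags by a binomial test, and the hypothesis was that each q is a tail probability with an even chance for either kind of tag, times the number of candidate regions, divided by the rank. With 16906 candidates, 10158 of 10159 q values matched exactly 1 pair of whole tag counts within a relative tolerance of 1e-11, 10157 of them at ranks 12 above their place in the list and the last only with its rank raised by 1 more. With 16905 or 16907 candidates 0 matched, and with all ranks 1 lower or higher 0 and 1 matched, the latter being that last peak. These checks searched only smaller tag totals than the main match did, so they do not cover the peaks with most tags. The ranks run to 10172, so 13 ranks belong to regions not analysed here, and 12 of these lie at the top, where they may be stronger than the peaks listed. The counts are inferred, cover both replicates together, and give input as scaled by the caller.

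On these inferred counts, the median peak had 296 ChIP tags and 136 input tags, and the median ratio was 2.04 (quartiles 1.65 and 2.73). The order by q differed in part from the order by ratio, with a Spearman's rho of 0.744 between −log10 q and ratio across peaks. Of the 1015 strongest peaks by q, 548 (54%) were also among the 1015 of highest ratio. The ratio is inferred from the same q values, so some overlap is built in. Of the peaks with at least 40 input tags, the highest ratio was 12.5, from 601 ChIP and 48 input tags, on I from 10744223 to 10744628 (q = 6.10e-121). The next was 12, on I from 14966812 to 14967309, and then 11.2, on II from 7242621 to 7243078. The peak on I from 6868119 to 6869296, among the 25 of lowest q, had a ratio of 11. A ratio under 1.5 was found for 1463 peaks and a ratio of 4 or higher for 777.

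The median inferred ratio was 1.93 on X and 2.07 on the autosomes (bootstrap of the difference −0.188 to −0.101; permutation p = 1e-05, the smallest possible). In peaks of at least 200 bp, input tags per kb had a median of 356 on X and 310 on the autosomes (difference 33.5 to 56.8). They were lower on IV, 277, than on the other autosomes, 319 (difference −53.4 to −32.0), and the ratio on IV was 2.15 against 2.05 (difference 0.0201 to 0.159; permutation p = 0.00046). Autosomal central peaks had a median ratio of 2.11 and arm peaks 1.98 (difference 0.0629 to 0.176). The other 3 of these 5 contrasts had a permutation p of 1e-05. Permutation treats peaks as independent, and the bootstrap does not. Input is the denominator of the ratio, and on X and on IV the ratio differed in the direction opposite to input. Only called peaks were counted, and whether the caller scaled input alike on all chromosomes is not known. The ratios on X and IV therefore cannot be read as weaker or stronger binding.

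The widest peak, 20797 bp on I from 10394082 to 10414878 (q = 1.73e-146), held 1179 inferred input tags per kb, 3.7 times the median and the highest of 9140 peaks of at least 200 bp. The next peak to the left, 253 bp away at 10390560 to 10393828, held 793.5 (percentile 99.23) at a ratio of 1.16, while the next to the right, 20810 bp away at 10435689 to 10436028, held 564.7 (percentile 93.87) at a ratio of 2.09. The input per kb of the widest peak was 1.86 times the highest of the 12 other peaks of at least 5000 bp, which argues against width alone, while its ratio of ChIP to input, 1.25, was low among all peaks (percentile 1.31) but within the 1.17 to 2.21 of those 12, of which 2 were lower, so broad binding stays open. A candidate explanation of the high input is that the strain carries extra copies of this DNA, possibly in the integrated blmp-1 transgene, since the gene table of WBcel235 also places blmp-1 on chromosome I; this would be decided by the WS180 positions of blmp-1 and of the ends of the transgene insert, which were not used here. Repeated sequence, a duplication elsewhere in the strain and open chromatin that enriches input were not tested and stay open.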
